A study of Mus musculus with 7 samples.

How the data were processed

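RNA was taken from part of the cortical plate at E14.5 and from a piece of it at 10.5 months, kept in a stabilising solution and isolated with a phenol reagent, per the labels' protocols. Libraries were made with the TruSeq RNA v2 kit at E14.5 and with the TruSeq stranded mRNA kit in adults, per the labels' protocols. The first kit does not mark the strand of a transcript and the second does. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.1.0, featureCounts 1.5.0 and the genome build GRCm38; the strand setting, the handling of reads with several matches and the annotation release are not given in the sources used here. The authors deposited whole-number read counts per gene, RPM values and RPKM values for 53801 genes in 7 libraries. From the values, the deposited RPM equalled counts divided by the library total, and the deposited RPKM used 1 length per gene in all libraries. Of the gene identifiers, 53706 were found in GENCODE M21, which is on GRCm38 and gave positions, gene types, exon lengths, GC content and overlaps with genes on the opposite strand. No row named anything but a gene, 66 rows had a blank symbol, and 20027 genes were at 0 in all libraries. The sheet held no other sample columns.

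Library totals were 32533065 to 43197226 counts at E14.5 and 27327927 to 29996018 in adults. Mitochondrially encoded genes took 2.26 ± 0.0624% of counts at E14.5 (SD, n = 4) and 8.13 ± 0.386% in adults (n = 3), and the 20 most abundant genes 5.25 ± 0.0883% and 11.9 ± 0.550%. Floors at 3 counts cover counting error only. Chi-square per degree of freedom between replicates of an age was 4.15 to 13.3, where sampling noise alone gives about 1.

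Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM factors, filterByExpr (minimum count 10, minimum total 15), age as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of F. A change beyond 2-fold was tested with glmTreat at a log2 threshold of 1. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 31 lists. The 31 lists, 6 gene pairs, tests and most alternatives were fixed before the data were examined. Genes named in the report were chosen by a rule fixed at the same time: Atr, Nbn and the pair members; the 5 largest rises and 5 largest falls with a mean of at least 10 CPM and no overlap between ages; for each list, the 2 largest called changes in the majority direction and the largest opposite one; and the 5 called genes with the largest sex difference. Some genes that this rule chose, and 1 of the pairs, are not reported here. Ezh1, Rad1, Rad17, Mre11a, Rad50, Ercc2 and Ercc4 were named after their values were seen. Pairs were compared by the difference in mean log2 ratio of CPM with 0.5 added, with an exact two-sided permutation test in SciPy 1.17.1. Sex was tested within the E14.5 libraries only.

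Alternatives were RLE, upper-quartile and total-count scaling, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, limma-trend on log2 of RPKM plus 0.5 or 0.1, each library left out, females only, sex as a covariate, the replicate number as a block, genes without opposite-strand overlap, camera with an estimated correlation, and fry. Chosen after the data were seen were protein-coding genes only, genes without opposite-strand exon overlap, genes without the mitochondrial genome, and offsets for GC content and length fitted per library with splines of 5 degrees of freedom. Processed pseudogenes were matched to their closest protein-coding transcript with BLAST 2.17.0. DESeq2 gave no adjusted p for 4 genes.

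The tests were checked on simulated counts drawn from the means, totals and dispersions of the real libraries, with 200 changed genes. For the age comparison, over 20800 genes, 42 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 62 of 66 changed 4-fold were recovered, with 10 false calls. For the sex comparison, over 20134 genes, 22 of 67, 44 of 67 and 64 of 66 were recovered, with 9 false calls. A list shifted 2-fold was recovered by camera and no other list was called. In these simulations most genes were unchanged and genes were drawn independently, whereas 86.4% of genes were called in the real data. The check therefore does not cover scaling under so wide a change, or correlation between the genes of a list.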

Results

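Gene expression was measured by RNA sequencing in mouse tissue labelled cortical plate at 2 ages, embryonic day 14.5 (E14.5) and 10.5 months. The E14.5 group held 4 libraries, from mice with 1 floxed Nbs1 allele and a Nestin-Cre transgene, of which replicates 1 and 4 were male and replicates 2 and 3 female. The adult group held 3 libraries, all female and all carrying a CamKII-Cre transgene, with 1 floxed Atr allele in replicates 1 and 3 and none in replicate 2. Nbs1 is an older name of Nbn, a subunit of the MRE11 complex that senses DNA double-strand breaks, and Atr encodes the kinase that responds to stalled replication forks. The libraries held 32533065 to 43197226 counts at E14.5 and 27327927 to 29996018 in adults. The labels give each library a sex and a genotype but do not say in so many words that each came from its own animal, so p-values measure the spread between these samples. E14.5 replicate 1 came from an earlier plug date than the other 3. For all 4, the labels' dates put brain isolation 12 days after the plug, fewer than the stated stage, and the stage is used here as labelled. Age could not be told apart from library kit, Cre driver or floxed allele, because none of these was shared between the ages. Spearman correlations of log CPM were 0.994 to 0.996 within an age and 0.774 to 0.790 between ages, and no pair of libraries agreed within sampling noise.

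Atr and Nbn, the genes that the genotypes name, moved in opposite directions. Each was lower at the age whose libraries carried its floxed allele, Nbn at E14.5 in all libraries and Atr in adults in most. For Nbn, age and genotype cannot be told apart. For Atr, only 1 adult library lacked the floxed Atr allele, and it still differed from the E14.5 libraries in Cre driver and floxed Nbs1 allele. Atr (ENSMUSG00000032409, GRCm38 chromosome 9, 95857597 to 95951781) had 33.2 ± 2.85 CPM at E14.5 (SD, n = 4) and 23.4 ± 1.799 in adults (n = 3), a log2 fold change of -0.51 (SE 0.082, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00014). Nbn (ENSMUSG00000028224, chromosome 4, 15957925 to 15992589) had 17.0 ± 1.49 CPM at E14.5 and 23.7 ± 0.681 in adults, a log2 fold change of 0.48 (SE 0.078, edgeR adjusted p = 0.00016). The single adult library without a floxed Atr allele had the highest adult Atr value, 25.3 CPM, against 22.9 and 21.8 in the libraries with one. It was also below every E14.5 library (30.4 to 36.3 CPM). The floxed Atr allele therefore cannot account for the lower level in that library, but this rests on a single library. The adult rise of Nbn did not pass the test with total counts as the only scaling (log2 fold change 0.064, edgeR adjusted p = 0.45; range of adjusted p over all settings 3.6e-08 to 0.45), whereas Atr fell under each setting run in which it was tested, with log2 fold changes from -0.46 (RLE scaling) to -0.92 with total counts only and -1.06 with GC and length offsets.

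**Figure D1:**
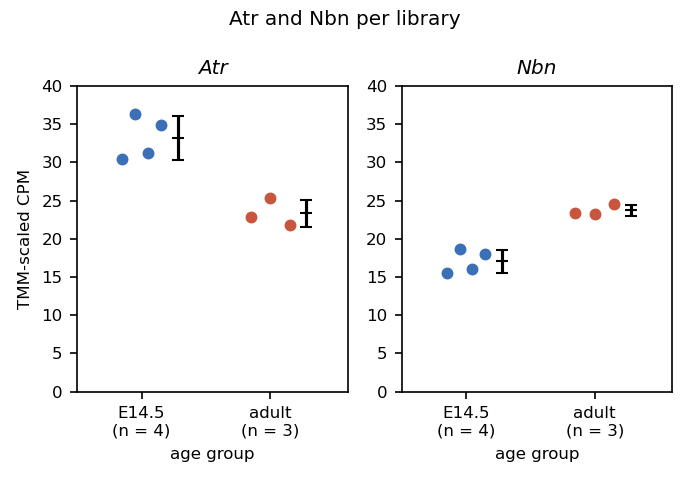
TMM-scaled CPM of Atr (left) and Nbn (right) in each library, by age group; points are libraries and black bars show the mean and SD of 4 E14.5 and 3 adult libraries. Adult libraries lie between 21.8 and 25.3 CPM for Atr, below the E14.5 libraries, and between 23.3 and 24.5 CPM for Nbn, above them.

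The comparison of the 2 ages asked which transcripts distinguish the embryonic from the adult tissue, labelled cortical plate at both ages. Whole pieces of tissue were sequenced, so changes within cells cannot be told apart from changes in which cells were present. Most progenitor, cell division and embryonic blood genes listed beforehand were lower in adults, and most synaptic, myelin and glial genes were higher. Eomes, the transcription factor of intermediate progenitors, had 303 ± 17.6 CPM at E14.5 and 0.0525 ± 0.0908 in adults (0 without adult replicate 1), and Mobp, a structural protein of myelin, had 0.0323 ± 0.0261 and 902 ± 47.1 CPM. Of 20800 genes tested, 17975 (86.4%) passed an adjusted p of 0.05, with 8683 higher and 9292 lower in adults. A test against a 2-fold change called 9824 genes, 5108 higher and 4716 lower. The balance depended on the scaling, with 5264 higher and 4528 lower with RLE factors, 4781 and 5223 with upper-quartile factors and 4130 and 6577 with total counts only. It was 4740 and 3720 with DESeq2, and 2726 and 4675, or 3535 and 5772, with limma-trend on log2 of RPKM plus 0.5 or 0.1, which changes the test along with the scaling. The libraries of the 2 ages did not overlap for 85.3% of genes, where chance gives 5.71%. The share of calls that were higher in adults was 48.3% with trimmed-mean (TMM) scaling, 49.8% with RLE, 44.7% with upper-quartile and 37.1% with total-count scaling, and 37.0% and 36.9% with limma-trend on the deposited RPKM with pseudocounts of 0.5 and 0.1. Total-count scaling moved the median log2 fold change of all genes from -0.08 to -0.49 and upper-quartile scaling to -0.20, and changes are given relative to TMM.

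The largest rises, among genes with a mean of at least 10 CPM and no overlap between ages, were in Mobp, Rps23-ps1, Gm6061, Fa2h and Gpr37l1. Fa2h, which makes hydroxylated myelin lipids, was at 0 in the 4 E14.5 libraries and at 38.4 ± 1.25 CPM in adults, at least 531-fold higher against a floor of 3 counts per library. Gpr37l1, a glial receptor, went from 0.0124 ± 0.0144 CPM (1 count in each of 2 libraries) to 159 ± 8.77 CPM. Rps23-ps1 and Gm6061 were also at 0 at E14.5, but 93.2% and 100% of their exon bases lie under exons of an opposite-strand gene, a class of gene often near 0 at E14.5 (bar plot of genes near 0). The largest falls by fitted log2 fold change were in Gm16216, Igf2bp3, Hbb-y, 4930516B21Rik and Gm26623. The order of such genes is loose, because the fitted value rests on few or no counts at 1 age. Eomes, for example, went from -12.3 to -16.4 without adult replicate 1, where Gm16216 had -13.7 with all libraries. Igf2bp3, a fetal messenger RNA-binding protein, had 47.8 ± 4.30 CPM at E14.5 and 0 in adults, at least 384-fold lower, and Hbb-y, the embryonic beta-like globin, went from 223 ± 55.8 to 0.0131 ± 0.0227 CPM (0 without adult replicate 1). Gm16216, 4930516B21Rik and Gm26623 were at 0 in all adult libraries and at 49.2 ± 2.26, 34.9 ± 1.18 and 33.6 ± 1.78 CPM at E14.5. Gm16216 is a processed pseudogene, and 32.4% of the exon bases of Gm26623, a long non-coding RNA, lie under exons of an opposite-strand gene.

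Progenitor and newborn neuron genes fell together. All 15 radial glia genes were lower in adults (median log2 fold change -2.42, camera adjusted p = 2.3e-11, and adjusted p = 0.036 with an estimated correlation). Fabp7, a fatty acid binding protein of radial glia, fell from 414 ± 27.7 to 10.2 ± 0.330 CPM, and Hmga2, a chromatin protein of early progenitors, from 22.4 ± 2.81 to 0.336 ± 0.158 CPM. Of 20 intermediate progenitor and newborn neuron genes, 18 fell and 1 rose (median -3.84, camera adjusted p = 4.6e-19, and adjusted p = 0.029 with an estimated correlation). Neurog2, a proneural transcription factor, fell from 210 ± 10.1 to 0.511 ± 0.102 CPM. Unc5d, a netrin receptor, was the member that rose, by a log2 fold change of 0.16 (SE 0.055, edgeR adjusted p = 0.021). However, it was -0.26 with total-count scaling (adjusted p = 0.00074) and did not pass without adult replicate 1 or 2 (adjusted p = 0.070 and 0.063). Nor did Unc5d pass with females only or with sex as a covariate (edgeR adjusted p = 0.14 in each). The same held with upper-quartile scaling, without the low-count filter and with protein-coding genes only (edgeR adjusted p = 0.60, 0.27 and 0.70). Counts adjusted over the list alone were also 15 of 15 and 18 lower with 1 higher.

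Layer markers moved both ways within each list and did not differ from other genes by camera. Among 8 deep-layer genes, 4 fell and 3 rose (camera adjusted p = 0.42), and among 8 upper-layer genes, 4 fell and 4 rose (camera adjusted p = 0.64). Fezf2, which specifies subcerebral projection neurons, fell from 152 ± 10.3 to 39.1 ± 3.08 CPM and Sox5 from 224 ± 31.6 to 47.2 ± 2.32, while Crym rose from 12.9 ± 0.817 to 54.4 ± 4.29. Rorb, a marker of layer IV, rose from 11.1 ± 1.97 to 73.8 ± 2.80 CPM and Lmo4 from 62.6 ± 7.61 to 227 ± 10.9, while Mdga1 fell from 154 ± 8.13 to 19.99 ± 3.49. For the upper layers the median was -0.20 and the mean 0.0066. The fry test, which does not compare a list with other genes, called both lists (adjusted p = 0.0013 and 0.019).

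Genes of mitosis and DNA replication showed the deepest median falls of the 31 lists. All 20 mitosis genes were lower in adults (median -6.94, camera adjusted p = 1.9e-28, but adjusted p = 0.079 with an estimated correlation). Ccnb1, the mitotic cyclin, fell from 118 ± 9.72 to 0.164 ± 0.0766 CPM and Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, from 83.8 ± 8.90 to 0.138 ± 0.0479. Of 22 DNA replication genes, 21 fell and 1 rose (median -4.45, camera adjusted p = 6e-18, but adjusted p = 0.16 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell from 176 ± 12.2 to 1.73 ± 0.0403 CPM. Fen1, the flap endonuclease, was listed as rising from 3.91 ± 0.576 to 12.5 ± 0.490 CPM (log2 fold change 1.68, SE 0.12, edgeR adjusted p = 1.6e-07), with 84.2% of its exon bases under exons of an opposite-strand gene. Both lists gave the same counts adjusted over the list alone.

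Of the 7 DNA damage response lists, 4 were called lower in adults and 3 were not called by camera. All 17 genes of ATR checkpoint signalling fell (median -1.51, camera adjusted p = 1.6e-05, but adjusted p = 0.26 with an estimated correlation). Clspn, the claspin adaptor, fell from 52.1 ± 7.04 to 1.40 ± 0.144 CPM and Chek1, the kinase that ATR activates, from 33.6 ± 3.75 to 2.39 ± 0.0980, whereas Rad17 and Rad1, parts of the clamp machinery, fell by 0.54 and 0.57 on the log2 scale. Of 14 genes of ATM and double-strand break signalling, 13 fell and Nbn rose (median -0.94, camera adjusted p = 0.0033, but adjusted p = 0.29 with an estimated correlation). Chek2 fell from 13.8 ± 1.51 to 1.35 ± 0.223 CPM and H2afx, which encodes the histone variant phosphorylated at breaks, from 144 ± 19.8 to 19.9 ± 1.43. The partners of Nbn in its complex were lower, Mre11a with a log2 fold change of -1.25 and Rad50 with -0.26. The E14.5 libraries carried the floxed Nbs1 allele and the adults did not, so for Nbn age and genotype cannot be told apart.

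Among the repair pathways, 19 of 20 homologous recombination and Fanconi anaemia genes fell and 1 rose (median -2.90, camera adjusted p = 7.6e-07, but adjusted p = 0.28 with an estimated correlation). Exo1, a resection nuclease, fell from 29.5 ± 3.82 to 0.387 ± 0.00913 CPM and Brip1, a helicase that binds BRCA1, from 9.44 ± 1.91 to 0.190 ± 0.127, while Rad51d rose from 11.1 ± 0.626 to 18.4 ± 1.93. Of 19 base excision and single-strand break repair genes, 15 fell and 1 rose (median -1.05, camera adjusted p = 0.0023, but adjusted p = 0.24 with an estimated correlation). Neil3, a DNA glycosylase, fell from 28.9 ± 2.86 to 0.0429 ± 0.0434 CPM (0.0643 and 0.0209 without adult replicates 1 and 2) and Ung, the uracil glycosylase, from 21.6 ± 1.40 to 1.31 ± 0.247, while Neil1 rose from 6.33 ± 0.391 to 9.71 ± 0.193. Non-homologous end joining (7 of 9 lower, 2 higher, camera adjusted p = 0.24), nucleotide excision repair (7 of 13 lower, 4 higher, camera adjusted p = 0.60) and mismatch repair (6 of 7 lower, 1 higher, camera adjusted p = 0.14) did not differ from other genes by camera. Xrcc6, the Ku70 subunit, fell from 47.3 ± 2.095 to 19.5 ± 0.386 CPM, Nhej1 from 3.70 ± 0.427 to 1.57 ± 0.420, Msh6 from 103 ± 6.91 to 26.6 ± 0.528, Ddb1 from 612 ± 20.4 to 283 ± 7.10 and Ercc8 from 20.9 ± 1.07 to 12.3 ± 1.25. Dclre1c (10.7 ± 1.006 to 14.3 ± 0.375 CPM), Mlh3 (15.3 ± 0.858 to 29.8 ± 2.54) and Ddb2 (6.34 ± 0.639 to 21.5 ± 1.11) rose. Exons of opposite-strand genes cover 23.8% of Ddb2 exon bases, and 42.4% of those of Ercc2, a list member that also rose, as did Ercc4. Counts adjusted over each list alone were identical in these 7 damage response lists. Dclre1c and Neil1 did not pass the test with total-count scaling (log2 fold changes 0.0048 and 0.20, edgeR adjusted p = 0.96 and 0.058), and the call for ATM signalling was lost without genes that have opposite-strand exon overlap (camera adjusted p = 0.056).

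**Figure D2:**
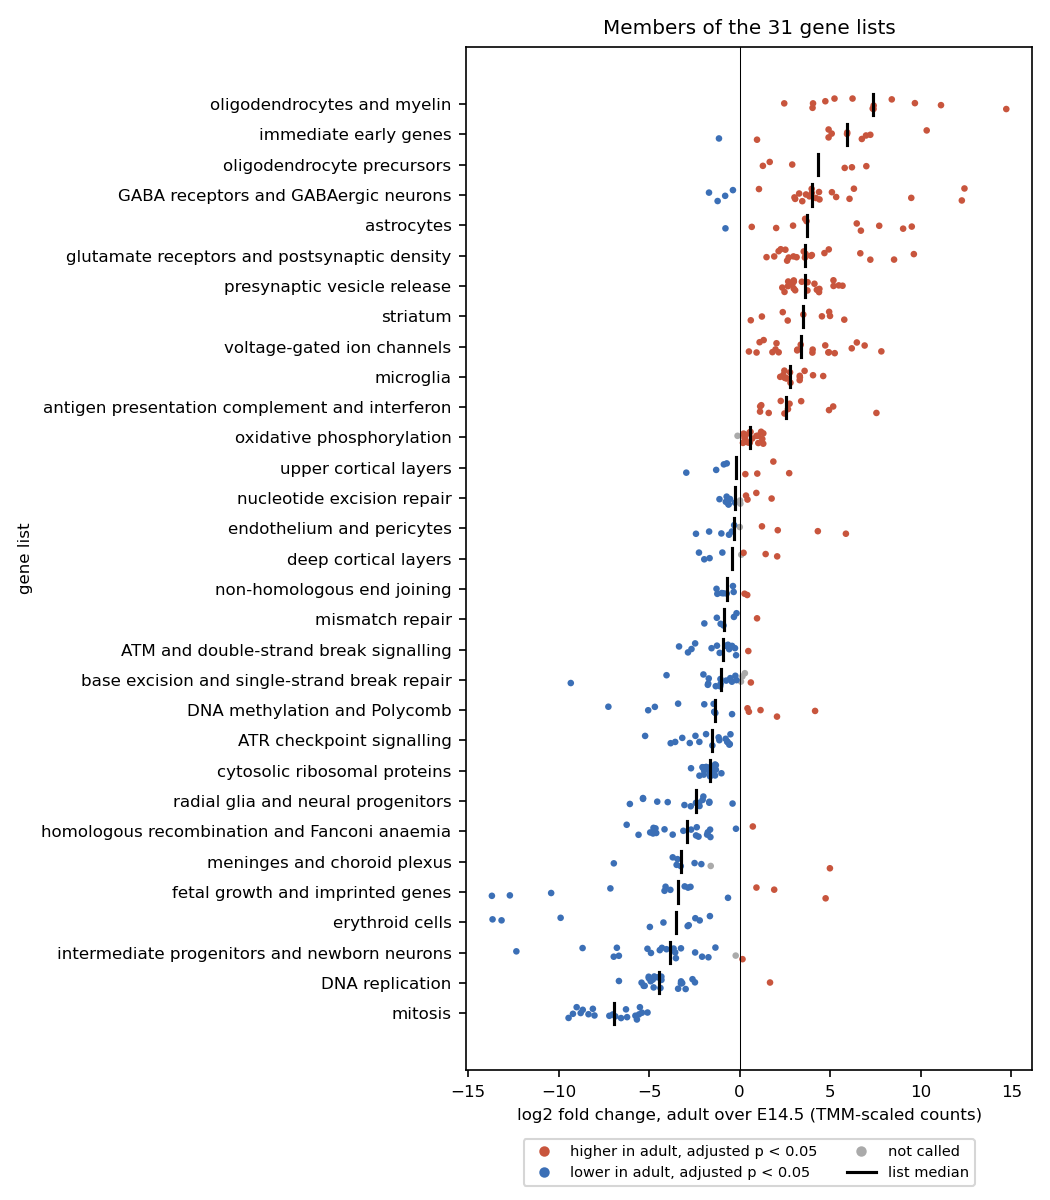
Log2 fold change, adult over E14.5, of each tested member (points) of 31 gene lists, ordered by list median (black bars); red and blue points passed an adjusted p of 0.05 upward and downward, grey points did not. Oligodendrocyte and myelin genes have the highest median, 7.35, and mitosis genes the lowest, -6.94. With total-count scaling each median is lower by about the shift of all genes, and no list median changes sign.

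Genes of neuronal transmission rose as groups. All 20 presynaptic genes (median 3.59), all 21 glutamate receptor and postsynaptic genes (median 3.60) and all 21 voltage-gated channel genes (median 3.37) were higher in adults, with camera adjusted p of 2.4e-19, 2.7e-16 and 5.4e-19. None of these calls held with an estimated correlation (adjusted p = 0.099, 0.079 and 0.079). Snap25, a SNARE protein of vesicle fusion, rose from 71.2 ± 6.35 to 3649 ± 142 CPM and Syt1, the calcium sensor of release, from 53.4 ± 14.3 to 2367 ± 133. Nrgn rose from 1.499 ± 0.239 to 1173 ± 83.6 CPM. Of 23 GABA receptor and GABAergic neuron genes, 19 rose and 4 fell (median 3.98, camera adjusted p = 1.3e-11, but adjusted p = 0.13 with an estimated correlation). Vip and Pvalb, markers of interneuron classes, had 52.3 ± 5.02 and 47.2 ± 2.76 CPM in adults and a single count over the 4 E14.5 libraries each, while Dlx2, which marks ventrally born interneurons and their progenitors, fell from 12.5 ± 8.16 to 3.89 ± 0.133. E14.5 replicate 1 had the highest Dlx2 level, and without it the E14.5 mean was 8.69 CPM, the log2 fold change -1.16 rather than -1.69 and the number of list genes that fell 3, as it also was without any 1 of the adult libraries. Of 11 immediate early genes, 10 rose and 1 fell (median 5.93, camera adjusted p = 0.00035, but adjusted p = 0.37 with an estimated correlation). Egr2 rose from 0.116 ± 0.0464 to 18.2 ± 8.58 CPM and Egr4 from 0.0218 ± 0.0315 (0.0069 without replicate 1) to 35.2 ± 9.55, while Ier2 fell from 24.4 ± 1.89 to 11.1 ± 1.76.

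Glial and immune genes rose as well. All 13 oligodendrocyte and myelin genes were higher in adults (median 7.35, camera adjusted p = 4.5e-27, and adjusted p = 0.0094 with an estimated correlation). Opalin, a myelin membrane protein, had 21.3 ± 2.07 CPM in adults and 1 count over the E14.5 libraries. Of 11 astrocyte genes, 10 rose and 1 fell (median 3.69, camera adjusted p = 7.1e-09, and adjusted p = 0.024 with an estimated correlation). Gfap, the astrocyte intermediate filament, rose from 0.427 ± 0.0194 to 225 ± 24.1 CPM and S100b from 0.174 ± 0.0425 to 128 ± 2.28, while Fgfr3 fell from 211 ± 30.6 to 123 ± 8.62. All 6 oligodendrocyte precursor genes (camera adjusted p = 0.012), all 14 microglia genes (1.5e-06) and all 12 antigen presentation, complement and interferon genes (0.0028) were higher in adults. Their adjusted p values with an estimated correlation were p = 0.30, p = 0.24 and p = 0.26. Gpr17 rose from 0.265 ± 0.167 to 35.2 ± 2.57 CPM, Olig1 from 1.12 ± 0.486 to 82.8 ± 9.80, Ctss from 3.38 ± 0.759 to 83.1 ± 4.601, C4b from 0.237 ± 0.0620 to 44.3 ± 4.73 and Ifit3 from 0.296 ± 0.0575 to 10.6 ± 0.373. The oligodendrocyte precursor call was lost without genes that overlap an opposite-strand gene (adjusted p = 0.24).

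Markers of tissues other than cortical neurons and glia also differed. All 10 erythroid genes were lower in adults (median -3.54, camera adjusted p = 0.00015, but adjusted p = 0.28 with an estimated correlation), with Hba-x at 33.0 ± 8.23 CPM at E14.5 and 0 in adults. Of 9 meningeal and choroid plexus genes, 7 fell and 1 rose (camera adjusted p = 0.048, but adjusted p = 0.41 with an estimated correlation). Col3a1, a fibrillar collagen, fell from 200 ± 39.7 to 1.62 ± 0.249 CPM and Col1a1 from 66.4 ± 16.6 to 5.14 ± 0.637, while Kl rose from 0.402 ± 0.154 to 12.9 ± 9.17. Adult replicate 3 carried much of the Kl value, with 23.5 CPM against 8.14 and 7.07 in the others, and without it the adult mean was 7.61 CPM and the log2 fold change 4.23 rather than 4.98. All 9 striatal genes were higher in adults (camera adjusted p = 0.048, but adjusted p = 0.53 with an estimated correlation), with Tac1 rising from 0.538 ± 0.472 to 17.6 ± 4.16 CPM (0.302 at E14.5 without replicate 1). The meningeal call was lost without adult replicate 1 (adjusted p = 0.057) and the striatal call without E14.5 replicate 2 (adjusted p = 0.051). Of 11 endothelial and pericyte genes, 6 fell and 4 rose, and the list did not differ from other genes (camera adjusted p = 0.86, median -0.30, mean 0.64). Kdr, the VEGF receptor of growing vessels, fell from 66.8 ± 4.00 to 12.5 ± 1.29 CPM and Cdh5 from 48.6 ± 6.56 to 15.1 ± 2.05, while Ly6c1 rose from 0.409 ± 0.141 to 23.5 ± 1.96.

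Growth, chromatin and metabolic genes completed the lists. Of 14 tested fetal growth and imprinted genes, 11 fell and 3 rose (median -3.43, camera adjusted p = 3.3e-05, but adjusted p = 0.094 with an estimated correlation). Igf2bp1 went from 115 ± 12.7 to 0.0139 ± 0.0241 CPM (0 without adult replicate 3), while Meg3, a maternally expressed non-coding RNA, rose from 180 ± 63.9 to 4829 ± 380. Of 15 DNA methylation and Polycomb genes, 10 fell and 5 rose (median -1.39, camera adjusted p = 0.020, but adjusted p = 0.41 with an estimated correlation). Uhrf1, which recruits the maintenance methyltransferase, fell from 162 ± 14.95 to 1.06 ± 0.0230 CPM and Ezh2, the Polycomb methyltransferase, from 261 ± 12.5 to 7.87 ± 0.577, while its paralog Ezh1 rose from 21.3 ± 0.644 to 88.8 ± 4.48 and Cbx7 from 4.27 ± 0.282 to 76.6 ± 5.62. All 20 cytosolic ribosomal protein genes were lower in adults (median -1.64, camera adjusted p = 2.5e-11, but adjusted p = 0.13 with an estimated correlation), with Rpl18 falling from 317 ± 6.56 to 49.2 ± 5.10 CPM. Of 20 nuclear oxidative phosphorylation genes, 19 rose (median 0.55, or 0.14 with total-count scaling, camera adjusted p = 0.034, but adjusted p = 0.41 with an estimated correlation), with Cox5b going from 57.4 ± 11.8 to 142 ± 5.91 CPM and Cox5a from 62.0 ± 8.55 to 153 ± 2.12. Adjusted over the list alone, 19 of these genes were higher and 1 lower. The lower quartile of their changes was 0.27 with TMM scaling, less than the drop in the median with total counts. The count of 19 therefore depends on the scaling. The oxidative phosphorylation call was lost without E14.5 replicate 2 (camera adjusted p = 0.052), and the fetal growth, Polycomb, oxidative phosphorylation, striatal and meningeal calls were lost without genes that overlap an opposite-strand gene (camera adjusted p = 0.085, 0.082, 0.085, 0.085 and 0.059). For the other lists the counts adjusted over the list alone equalled those adjusted over all genes.

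Pairs of genes whose balance is known to shift during brain development were compared within each library, as the log2 ratio of the adult over the embryonic member. The ratio was higher in every adult library than in every E14.5 library for the 5 pairs given here. It rose by 5.37 for Slc12a5 over Slc12a2, chloride transporters, from -2.73 ± 0.379 (SD, n = 4) to 2.65 ± 0.072 (n = 3). The ratio of Grin2a over Grin2b, subunits of the NMDA receptor, rose by 4.22, from -4.81 ± 0.226 to -0.60 ± 0.038, and that of the sodium channels Scn1a over Scn3a by 3.73. The size for Grin2a depended on the value added, since its E14.5 level was 0.773 CPM: the change was 4.74 with 0.1 CPM added, 3.16 with 2 CPM added and 1.82 on RPKM. For Actl6b over Actl6a, subunits of the BAF chromatin remodelling complex, the change was 3.14, and for Dlg4 over Dlg3, postsynaptic scaffolds, 0.80. Each pair had an exact two-sided permutation p of 0.057. The test doubles the one-sided p, and this is the smallest value it can give for 4 against 3 libraries. No pair could therefore pass 0.05 by this test. Among these genes only Actl6a fell (91.7 ± 5.19 to 14.3 ± 0.304 CPM), and the embryonic members Grin2b, Dlg3, Slc12a2 and Scn3a rose along with their adult partners. The rise of Actl6b (56.4 ± 6.86 to 79.8 ± 4.21 CPM) did not pass the test with total-count scaling (log2 fold change 0.09, edgeR adjusted p = 0.38).

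**Figure D3:**
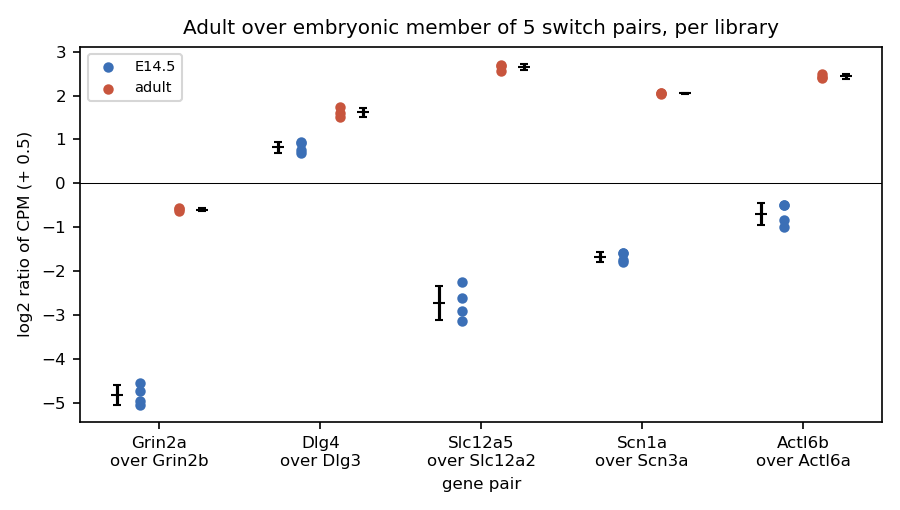
Log2 ratio of CPM (with 0.5 added) of the adult over the embryonic member of 5 gene pairs in each library; blue and red points are E14.5 and adult libraries, black bars the mean and SD of 4 and 3 libraries. For each pair the adult points lie above the E14.5 points, by 0.80 for Dlg4 over Dlg3 and by 5.37 for Slc12a5 over Slc12a2.

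Sex differences could be tested within E14.5, with 2 male and 2 female libraries. Of 20134 genes, 10 passed an adjusted p of 0.05, 5 higher in males and 5 higher in females. An unadjusted p under 0.05 was found for 590, fewer than chance alone would give over that many genes. The Y-linked genes Uty, Eif2s3y, Kdm5d and Ddx3y had 31.4 ± 2.45, 82.4 ± 0.0798, 56.5 ± 11.3 and 57.7 ± 4.99 CPM in males (SD, n = 2) and at most 0.136 CPM on average in females. Xist, the RNA of the inactive X chromosome, had 1060 ± 16.4 CPM in females and 2.31 ± 0.866 in males. In all 7 libraries the levels of these 5 genes matched the sex in the labels. The number of calls was 52 with DESeq2. Leaving out 1 library leaves 1 sex with a single library, assumed to vary like the other sex, and gave 44 and 55 calls without E14.5 replicates 1 and 4 and 6 without either replicate 2 or 3.

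Genes almost covered by exons of an opposite-strand gene were near 0 at E14.5 more often than other genes. Of 39 genes with a mean of at least 1 CPM and at least 90% of exon bases under opposite-strand exons, 26 (66.7%) were at 3 counts or fewer in each E14.5 library and 1 (2.56%) in each adult library. Among 12398 genes without such overlap, 77 (0.621%) and 128 (1.03%) were. Without genes that have any opposite-strand exon overlap, 12922 of 15153 genes tested were called, 7085 of them beyond 2-fold.

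**Figure D4:**
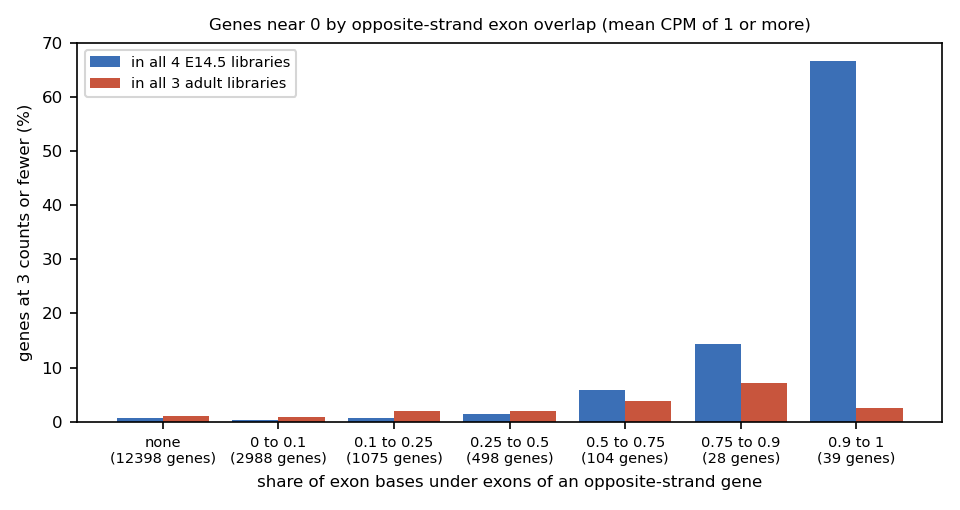
Percent of genes (vertical axis) at 3 counts or fewer in all 4 E14.5 libraries (blue) or all 3 adult libraries (red), by the share of a gene's exon bases that lies under exons of an opposite-strand gene, among genes with a mean of at least 1 CPM. The share in E14.5 reaches 66.7% in the class of highest overlap, against 2.56% in adults.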

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

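Each of 136 values was checked for a library far from the other 3 of the E14.5 group, by the ratio of its gap from the nearest library to the range of the group (Dixon's test at the 95% level), and 7 values met this, where chance gives about 6.8. Adult values, in a group of 3, were not checked. E14.5 replicate 1, the library from the earlier plug date, stood apart in 5 of the 7. The values are not independent of each other, and a single library does not separate its date from other differences between samples, so no explanation was tested. Its Sox5 level was 177.1 CPM against 236.6 to 244.5 in the others, its Ctss level 4.513 CPM against 2.932 to 3.098, and its Tac1 level 1.245 CPM against 0.2888 to 0.3274. The percent of its counts in mitochondrially encoded genes was 2.357 against 2.222 to 2.241, and its Pvalb level was 0.02223 CPM, a single count, against 0 in the others. Vip and Opalin were at 0.02625 CPM, again 1 count each, in E14.5 replicate 3 and at 0 in the others. A gene with 1 count in a single library and 0 in the others meets this test by construction. The 6.8 given for chance does not allow for such values. Without replicate 1, 17690 genes were called for age and 9744 beyond 2-fold.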

How the results depend on the processing

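The GC and length offsets and the limits to protein-coding genes, to genes without opposite-strand exon overlap and to genes outside the mitochondrial genome were chosen after the data were seen. Of 98 named genes, 93 kept their direction and side of the threshold under all settings that tested them, and of the 31 lists 5 did. With an estimated correlation 4 of the 25 called lists held, while fry, which does not compare a list with other genes, called 30. List calls were lost under 1 or more other settings for oligodendrocyte precursors, meninges, striatum, fetal growth, Polycomb, oxidative phosphorylation and ATM signalling. Leaving out 1 library gave 17556 to 17731 genes, 9547 to 9803 beyond 2-fold and 23 to 25 lists. All 6 pairs stayed fully separated under each pseudocount, on RPKM and without any 1 library, while the change for Grin2a over Grin2b ranged from 1.82 on RPKM to 4.74 with 0.1 CPM added. Depth limits genes with a few counts, such as Vip, Pvalb and Opalin at E14.5, to bounds.

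Without genes overlapping an opposite-strand gene, which leaves 12129 genes to test, 10285 were called (4934 higher, 5351 lower) and 5539 beyond 2-fold (2829 higher, 2710 lower). With protein-coding genes only, 3848 were higher and 3050 lower beyond 2-fold, again from fewer genes tested. On log2 of RPKM plus 0.5, 2726 were higher beyond 2-fold. Nbn had a log2 fold change of 0.0639 with total counts only and of 0.0627 and 0.0660 on RPKM plus 0.5 and 0.1, short of the threshold in each. Unc5d reversed with total counts only (-0.26), on RPKM plus 0.5 and 0.1 (-0.24 and -0.25) and with GC and length offsets (-0.12), and Dclre1c reversed with those offsets (-0.022). Atr had -1.06 with the same offsets. The cause of the Nbn, Unc5d, Dclre1c and Atr shifts was not tested. Sex calls numbered 27 without the low-count filter, 52 with DESeq2, 28 with all 7 libraries in one fit and 6 to 55 leaving out 1 library, where the spread comes from the sex with 2 libraries. The cause was not tested. With the replicate number as a block, 17669 genes were called, 17505 of them among the 17975 called without it. Deviations of same-numbered libraries correlated at -0.0013, -0.015 and 0.028, within the -0.064 to 0.071 of the other pairs of libraries. The labels do not say whether the numbers pair the samples, and these values cannot decide it.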

Other observations

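In this part, the gene families and the tests of strand counting, of GC content and length, of the library kit and of other splits of the libraries were chosen or worded after the results were seen, as were the genes named other than Fen1 and Dlx2. The tests of pseudogenes against their parents were set out beforehand. All 15 circadian clock genes tested were higher in adults (median log2 fold change 3.404, or 2.99 with total-count scaling, camera adjusted p = 1.4e-12, and adjusted p = 0.021 with an estimated correlation). The count of 15 was taken with TMM scaling only. Dbp, an output transcription factor of the clock, rose from 3.82 ± 0.604 to 112 ± 6.64 CPM, Bhlhe41 from 0.746 ± 0.299 to 66.1 ± 5.13 and Per1 from 27.3 ± 1.84 to 169 ± 22.3, while Cry1 rose least, from 21.9 ± 0.455 to 28.4 ± 4.21. Of 24 neuropeptide and peptide-processing genes, 22 rose and Nxph4 fell (median 4.04, camera adjusted p = 1.2e-07, but adjusted p = 0.15 with an estimated correlation), with Cck rising from 3.09 ± 0.610 to 200 ± 14.8 CPM. Of 67 protocadherins, 58 rose and 5 fell (median 1.42, camera adjusted p = 0.00015, but adjusted p = 0.21 with an estimated correlation). The exceptions included Pcdh12 and Pcdh18, with log2 fold changes of -5.57 and -2.96.

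Splicing and translation factors moved the other way. Of 31 hnRNP and SR genes, 25 fell and 4 rose (median -1.09, camera adjusted p = 6.1e-06, but adjusted p = 0.34 with an estimated correlation), with Hnrnpa1 falling from 1550 ± 65.2 to 294 ± 11.7 CPM. Of 65 translation initiation and elongation genes, 50 fell and 11 rose (camera adjusted p = 0.00013, but adjusted p = 0.12 with an estimated correlation). Within that family Eef1a1 fell from 5851 ± 33.2 to 1429 ± 33.4 CPM while Eef1a2, the elongation factor form of mature neurons and muscle, rose from 30.9 ± 5.82 to 896 ± 39.3. Of 25 chromatin remodellers, 19 fell and 4 rose (camera adjusted p = 0.0026, but adjusted p = 0.39 with an estimated correlation), with Chd7 falling from 134 ± 13.6 to 15.6 ± 0.741 CPM and Chd5 rising from 32.7 ± 8.63 to 376 ± 12.4. Of 13 mitochondrially encoded messenger RNAs, 12 rose (median 2.06, camera adjusted p = 3.1e-05, but adjusted p = 0.34 with an estimated correlation). Axon guidance genes (26 higher and 31 lower of 68), collagens (19 and 21 of 43), replication-dependent histones (5 and 19 of 40) and heat shock genes (37 and 29 of 76) did not differ from other genes by camera, with adjusted p of 0.32, 0.24, 0.36 and 0.23. No median of a called family changed sign with RLE, upper-quartile or total-count scaling, while that of the heat shock genes went from 0.12 to -0.29 with total counts.

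Genes almost covered by opposite-strand exons were listed near 0 in E14.5 in 66.7% of cases, against 0.621% of genes without overlap (Fisher's exact p = 1.8e-46). Age as the sole source of this class is argued against, because near-0 genes split between E14.5 and adult as 26 to 1 here and as 77 to 128 without overlap (Fisher's exact p = 1.59e-09). A candidate explanation is that reads on exons of both strands were left unassigned in the E14.5 libraries, whose kit does not mark strand, and assigned in adults. In the mirror case, non-coding genes within 5 kb of an opposite-strand gene were near 0 in adults more often than distant ones (odds ratio 5.93, Fisher's exact p = 2.2e-05), in line with E14.5 reads of a neighbour counted without strand. By this hypothesis the listed rises of Fen1 (84.2% covered) and Med10 (at most 1 count in E14.5 libraries, 635 to 770 in adults) and the fall of mt-Nd6 (377 ± 19.9 to 33.5 ± 4.97 CPM), the 1 mitochondrial messenger RNA that fell and the 1 on the other strand, may come from counting, and age stays open for each gene.

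Processed pseudogenes were mostly lower in adults, 2074 of 3061 falling and 446 rising. With transcribed ones included, 3069 of 3185 matched a protein-coding transcript, at a median identity of 95.9%. The 647 whose parent rose had a median log2 fold change of 0.44 (95% bootstrap interval 0.38 to 0.48), and the 2257 whose parent fell had -1.47 (-1.52 to -1.43). Across pseudogenes, which are not independent replicates, the Spearman correlation with the parent was 0.745, and the highest of 1000 shufflings of parents was 0.063. This argues against a fall of pseudogenes whatever their parent does and is consistent with reads shared with the parent, so fold changes of single pseudogenes stay uncertain.

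The age difference over most genes kept 89.0% of its calls, in direction and threshold, with offsets for GC content and length, which argues against those trends as its whole source. Age and library kit cannot be told apart, since 0 kits were used at both ages, and Cre driver and floxed allele are confounded in the same way. Of the 35 splits of the 7 libraries, 1, the real one, gave as many as 17975 genes, the highest other giving 0. Beyond 2-fold, 1 gave as many as 9824, the highest other again giving 0. Every other split puts libraries of both ages in 1 group, which adds the age difference to the spread within that group. Those splits were therefore bound to give few calls, and they do not exclude chance. For the lists, 1 of 35 splits called as many as 25, but the others called 11 to 24 while calling 0 genes. Those splits are each unbalanced for age, so they do not show how many lists camera calls without an age difference. With an estimated correlation 4 of the 25 called lists held. The number of lists called by camera at a preset correlation is therefore weak evidence by itself. The counts of genes within each list do not rest on camera.

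Other values are given without explanation. Ttr, a choroid plexus transcript, had 176 CPM in E14.5 replicate 4 against 583 to 668 in the other 3, and 437 CPM in adult replicate 3 against 46.0 and 17.4 in the others. Folr1 had 2.44 CPM in E14.5 replicate 4 against 8.43 to 9.77, and 2.97 in adult replicate 3 against 0.354 and 0.564. E14.5 replicate 1 had the highest level of that group for 5 transcripts of ventral and GABAergic cells: Dlx2 (24.1 CPM against 6.44 to 12.5 in the other 3), Dlx1 (83.2 against 32.4 to 53.5), Dlx5 (8.83 against 2.87 to 4.46), Gad1 (30.7 against 12.4 to 20.4) and Gad2 (30.8 against 12.5 to 17.9). Dlx5 in E14.5 replicate 2 lay within the adult values of 2.8 to 3.08 CPM. Drd2 had 13.7 CPM in adult replicate 3 and 6.33 and 7.81 in the others. The 5 autosomal genes called for sex at E14.5, named after their values were seen, were Rec8, 9330104G04Rik, Slc1a5 and Gm5948, higher in females, and Hjurp, higher in males at 230 ± 16.7 against 121 ± 5.75 CPM (SD, n = 2, scaled within E14.5). Of these, 9330104G04Rik (16871347 to 16874886) and Slc1a5 (16781340 to 16798274) are neighbours on chromosome 7. Hjurp had 28.1 CPM in adult replicate 2 and 68.5 and 63.9 in the other adults.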
